A study of Mus musculus with 13 samples.

How the data were processed

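RNA was measured by sequencing of polyA-selected libraries made with a NEBNext Ultra kit from TRIzol extracts of whole tissue, per the labels' protocols. The values are whole-number read counts per gene symbol as the authors deposited them, in 1 table of 38279 symbols and 10 libraries, with no scaling between libraries visible in the totals. The submitters' processing notes name Salmon 1.2.0, DESeq and the mm9 build, without saying what each was used for. How transcripts were summed to genes is not given in the sources used here. If the counts are rounded estimates from Salmon, reads of near-identical genes were divided by its model. No coordinates are given, because the annotation at hand is for another build, and 97.2% of the symbols matched it by name.

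Groups were taken from the labels: 4 wild-type glands and 6 tumours. Of 13 samples in the series, the 3 of purified epithelium were not analysed here. The tumours and glands differ in genotype, tissue state and age at once. Glands 1 to 3 carry identifiers of another form than gland 4 and the tumours. The sequencing run of each library was not known here, so a difference in run between the groups cannot be told apart either. The labels give each library its own identifier but do not say in so many words that each came from its own animal, so p-values measure the spread between these libraries. No 2 libraries were copies: over 45 pairs the lowest chi-square per degree of freedom was 37.8, for genes with a summed count of at least 20, and the highest Spearman correlation was 0.938. Both values belong to glands 2 and 3, and the next lowest chi-square was 155, for glands 1 and 3. The tests treat all libraries as independent. Total counts per library were 32548237, 48353114, 13723065 and 27141874 in glands 1 to 4 and 34865913, 48325044, 45505300, 45391449, 38188173 and 36236732 in tumours 1 to 6. Salivary transcripts left fewer counts for other genes in tumours 1 and 6.

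Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (20101 of 38279), scaled by TMM and tested with the quasi-likelihood F test, tumour against gland, with no covariate. The TMM factors of tumour 1 and gland 4 were 0.422 and 0.580, against 0.889 to 1.41 in the others. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of F. Levels are TMM-scaled CPM, given as mean ± SD, while shares of counts use all counts of a library. The biological coefficient of variation was 0.707. Tested on simulated data with the same design and 200 changed genes over 19302 tested genes, the edgeR test recovered 0 of 67 genes changed 2-fold, 11 of 67 changed 4-fold and 39 of 66 changed 8-fold, with 2 false calls. DESeq2 recovered 3, 45 and 58 of these, with 49 false calls. A gene that misses the edgeR threshold may therefore still differ. Calls by DESeq2 were more often false than those by edgeR in this simulation, which limits its larger counts below.

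Gene lists for 12 pathways or processes and 15 cell types were written from general knowledge, and lists with at least 5 tested members were tested with camera (limma 3.58.1), with a preset inter-gene correlation of 0.01, adjusted over 26 lists. The test was repeated with estimated correlations and with fry. Camera looks for a shift in a shared direction, so a list whose members moved both ways can fail it. A mixed form of fry looks for change in either direction. Fry tests the members alone and does not set them against other genes. Estimated correlations were high, 0.902 for mitosis genes and 0.766 for E2F targets, and no list passed with them. The E2F and mitosis lists each share 1 gene with the list of Fbxw7 substrates.

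The named genes were chosen by a rule: Fbxw7, Myc, Ccne1, E2f1, Trp53, Cdkn1a, Mdm2, Notch1 and Jun whatever their test, the 8 highest and 8 lowest fold changes among called genes above the median level whose groups did not overlap (unnamed gene models, mitochondrial genes and antigen receptor segments excluded), and from each list up to 3 called members with the smallest adjusted p in each direction. Of the 88 genes this gave, a part is named. Groups, tests, lists, this rule and most alternatives were fixed before the data were examined. The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter and a stricter filter, a 2-fold threshold, age as a covariate and leaving out each library. The salivary marker list and 3 further choices of libraries were added after the data were seen. In 20 salivary markers, 4 (Amy1, Aqp5, Klk1 and Egf) were above a mean of 1 CPM in the glands, before TMM scaling.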

Results

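Gene-level read counts were analysed for 10 mouse mammary libraries, 6 from mammary tumours of Cre-positive mice and 4 from whole mammary glands of Cre-negative (wild-type) mice. Fbxw7 encodes the substrate-recognition subunit of an SCF ubiquitin ligase, and in the Cre-positive mice its excision was induced by mating at 12 weeks of age. The labels give the same mating age for the wild-type glands. Glands 1 to 3 came from animals of 20 weeks and gland 4 from an animal of 40 weeks. The tumours came from animals of 25, 32, 39, 19, 53 and 25 weeks (tumours 1 to 6). Total counts ranged from 13723065 (gland 3) to 48353114 (gland 2). The comparison of tumours with glands bears only in part on the series title, which links Fbxw7 loss to E2F and c-Myc activity and to Trp53 mutation. It does not separate Fbxw7 loss from tumour state, age, tissue make-up and a possible sequencing batch. RNA levels do not measure the protein levels of the ligase's substrates. Mutations were not analysed here.

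Fbxw7 itself was at 33.5 ± 33.4 CPM in the glands (SD, n = 4) and 30.9 ± 10.4 CPM in the tumours (SD, n = 6), a log2 difference of -0.12 with a standard error of 0.51 (adjusted p = 0.888, edgeR). The gland mean was set by gland 4, at 83.6 CPM, against 14.3, 17.8 and 18.4 CPM in glands 1 to 3. Without gland 4 the log2 difference was 0.80 (adjusted p = 0.135). The labels do not say which exons are excised, and counts from exons outside the excised part remain in a gene total, so this level is no check of the genotype labels.

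Marker transcripts of other tissues differed between libraries of 1 group. In tumour 1, 62.2% of all counts came from a list of 20 salivary gland markers chosen after the values were seen, and in tumour 6 the share was 22.0%, against 0.0152% to 0.0446% in tumours 2 to 5. Bpifa2, a secreted salivary protein, alone took 34.9% of the counts of tumour 1 and 11.8% of those of tumour 6. Skeletal muscle markers took 9.02% of the counts in gland 4, 1.73% in gland 1, 0.805% in gland 2 and 0.00493% in gland 3. Mitochondrial transcripts made up 37.5% of the counts of gland 4 and 8.07% to 14.0% of those of the other 9 libraries.

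**Figure D1:**
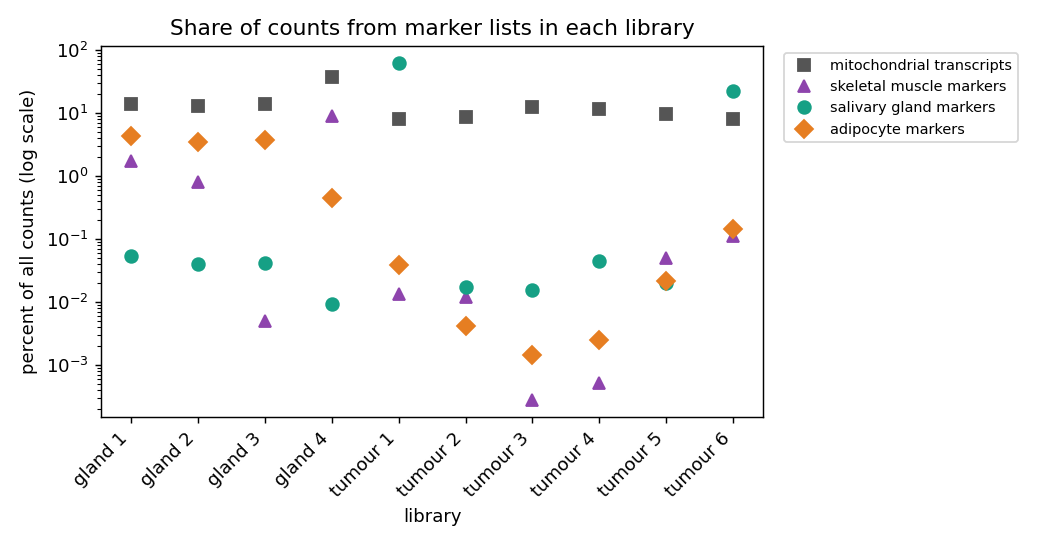
Percent of all counts (log axis) taken by mitochondrial transcripts and by the skeletal muscle, salivary gland and adipocyte marker lists, with one symbol per list for each of the 10 libraries. Salivary gland markers reach 62.2% in tumour 1 and 22.0% in tumour 6, and mitochondrial transcripts reach 37.5% in gland 4.

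Tumours differed from glands in 3030 of 20101 genes tested, with 1384 higher and 1646 lower in tumours (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05, two-sided). Of these, 1358 higher and 1591 lower genes differed at least 2-fold. In 2823 genes (14.0%) no tumour library overlapped any gland library, where chance gives 0.952%. The split depended on the scaling: upper-quartile factors gave 1809 higher and 1313 lower, and moved the median log2 fold change of all tested genes by 0.16. Leaving out gland 1, 2 or 3 or tumour 2 or 4 lowered the count to 1053, 1496, 1769, 2006 and 1837, and without tumours 1 and 6 it was 4255. Tumours against gland 4 alone, a choice made after the data were seen, gave 330 genes, 5 higher and 325 lower.

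Genes of cell division rose in tumours. Of 26 mitosis genes, 24 were higher over all genes tested and 26 when adjusted over the list alone, with a median log2 fold change of 3.21. Birc5, a regulator of chromosome segregation and cell survival, rose from 2.11 ± 1.14 CPM (SD, n = 4) to 41.9 ± 40.6 CPM (SD, n = 6), a log2 fold change of 4.30 ± 0.81 (SE; adjusted p = 0.00936). The kinetochore gene Cenpf rose by 3.62 ± 0.71 and Hmmr, a spindle-associated protein, by 3.07 ± 0.56 on the log2 scale (adjusted p = 0.0107 and 0.00855). Of 36 E2F targets, 17 were higher and none lower, 32 higher when adjusted over the list alone, and the median log2 fold change was 1.91. Among them Tyms, needed for thymidylate synthesis, rose by 2.50 ± 0.48 and the replication origin factor Orc1 by 3.33 ± 0.72 (adjusted p = 0.00991 and 0.0152). The Orc1 call was lost without gland 1 (adjusted p = 0.0544). Both lists passed the set test with a preset correlation (adjusted p = 2.62e-15 for mitosis and 5.26e-12 for E2F targets, camera). With an estimated correlation the adjusted p was 0.463 for both. With fry it was 0.0406 for mitosis and 0.0570 for E2F targets. Markers of luminal epithelium rose beside these lists (median 2.21) and those of adipocytes fell (median -6.15). Tumour 1, with its salivary transcripts, was the tumour with the lowest summed levels of mitosis genes, at 117 CPM, and of E2F targets, at 276 CPM. These E2F sums lay between 682 and 3144 CPM in the other 5 tumours and between 223 and 381 CPM in the glands.

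**Figure D2:**
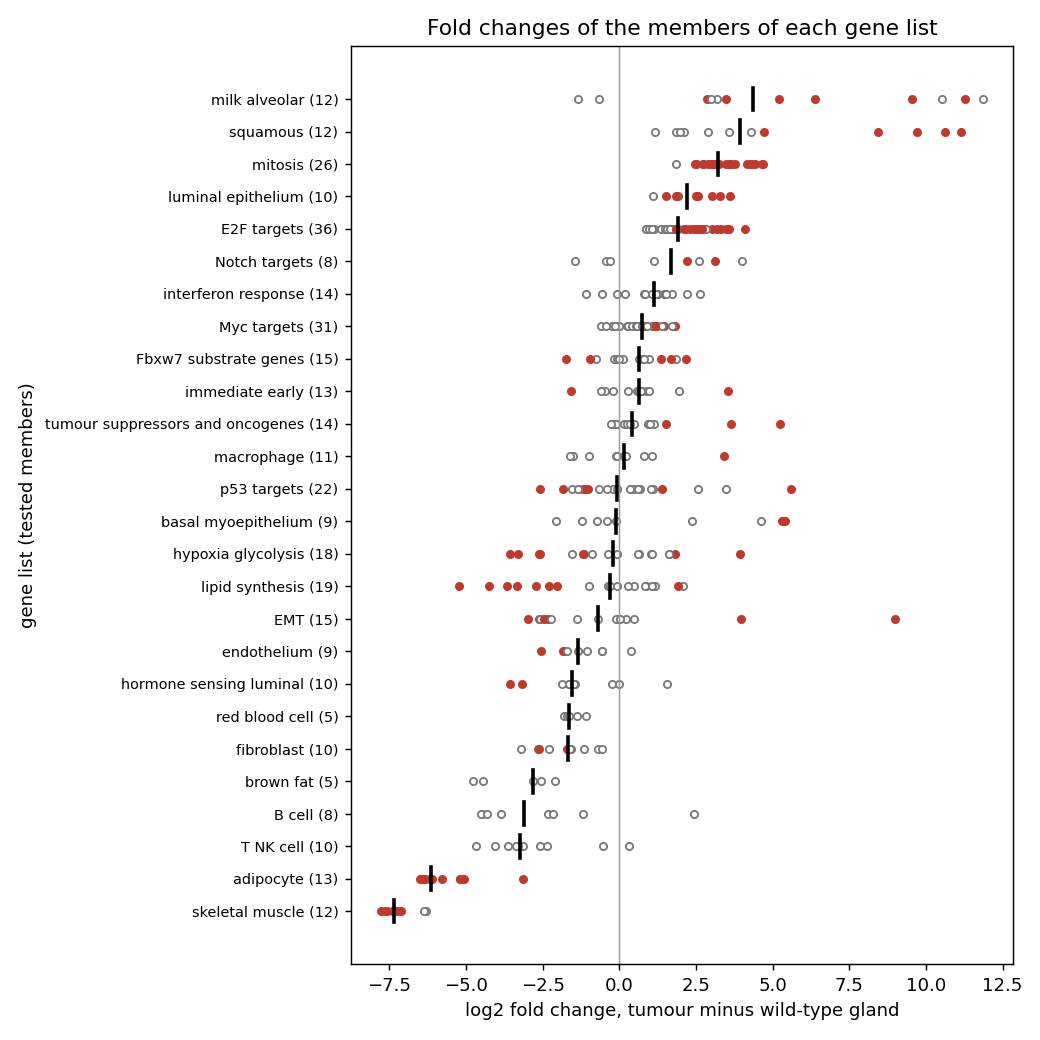
Log2 fold change (tumour minus wild-type gland) of every tested member of 26 gene lists, with filled points for members past an adjusted p of 0.05 and black bars at list medians. Medians run from -7.34 for skeletal muscle to 4.35 for milk genes, with mitosis genes at 3.21 and E2F targets at 1.91.

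Myc, whose protein is a substrate of the Fbxw7 ligase, was at 15.7 ± 4.81 CPM in glands (SD, n = 4) and 40.0 ± 16.3 CPM in tumours (SD, n = 6), a log2 fold change of 1.35 ± 0.40 (SE; adjusted p = 0.0419). It lay above every gland in 5 of 6 tumours, with tumour 1 at 14.7 CPM. Of the 10 fits without 1 library the call held in those without tumour 1 or tumour 5. It was lost in the other 8, without any 1 gland or tumour 2, 3, 4 or 6, with log2 fold changes over all 10 of 1.2 to 1.5 and adjusted p of 0.0133 to 0.133. It was also lost with no filter, with age as a covariate and with limma-voom (adjusted p = 0.0810, 0.0682 and 0.0540). Of 31 Myc targets, mostly genes of ribosome assembly, 6 rose and none fell, 8 when adjusted over the list alone, with a median of 0.75 (camera adjusted p = 0.00236, and adjusted p = 0.463 with an estimated correlation). Luminal epithelial markers rose in the same libraries (median 2.21), and a larger share of epithelial cells was not tested as a cause for Myc targets. Cdk4, a cell cycle kinase, rose by 1.81 ± 0.43, and Gar1, of small nucleolar ribonucleoproteins, by 1.16 ± 0.30 (adjusted p = 0.0216 and 0.0275). Both calls were lost without any 1 of the glands, and that of Gar1 also without tumour 4 or 6 (adjusted p up to 0.0700 and 0.0947). Ccne1, the cyclin E1 gene, and E2f1 had log2 differences of 0.96 ± 0.70 and 0.88 ± 0.46 (SE; adjusted p = 0.345 and 0.200), and 0.60 and 0.56 without gland 4. Without tumour 4 that of Ccne1 was 0.61.

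Among 15 genes whose proteins are Fbxw7 substrates, Myc, Klf5 and Tgif1 rose and Nfe2l1 and Mtor fell, also when adjusted over the list alone. Klf5, an epithelial transcription factor, changed by 2.16 ± 0.59, Tgif1 by 1.68 ± 0.45, Nfe2l1 by -1.74 ± 0.33 and Mtor by -0.94 ± 0.24 (SE; adjusted p = 0.0341, 0.0311, 0.00939 and 0.0273). The Klf5 and Mtor calls were lost without gland 1 or 2, among other libraries, with adjusted p up to 0.102 and 0.0972, and the Tgif1 call without any 1 of the glands or tumour 2 or 4, with adjusted p up to 0.0944. The list as a whole did not shift in a shared direction at the RNA level (camera adjusted p = 0.501). For change in either direction it passed (mixed fry adjusted p = 0.000279). Protein levels were not measured. Notch1 and Jun, both on that list, had log2 differences of 0.64 ± 0.60 and 0.13 ± 0.39 (adjusted p = 0.469 and 0.833), that of Notch1 0.26 without gland 4 and 0.26 to 0.93 over all fits without 1 library. Of 8 tested Notch targets, Hes1 and Nrarp rose, by 2.21 ± 0.59 and 3.12 ± 0.89 (adjusted p = 0.0306 and 0.0395), 5 rose when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.131). The Hes1 call was lost without gland 1, 2 or 3 or tumour 2 or 4, and the Nrarp call without any 1 gland or tumour 2, 3 or 5 (adjusted p up to 0.0959 and 0.109).

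Trp53 was at 22.0 ± 9.53 CPM in glands and 42.3 ± 21.4 CPM in tumours, a log2 difference of 0.94 ± 0.47 (SE, n = 4 and 6; adjusted p = 0.181). Without tumours 1 and 6 it passed, at 1.25 (adjusted p = 0.0455, over all alternatives 0.0455 to 0.569). Its targets Cdkn1a, a cell cycle inhibitor, and Mdm2, a p53 ubiquitin ligase, differed by 1.10 ± 0.94 and -0.06 ± 0.34 (adjusted p = 0.419 and 0.914). Cdkn1a was at 2.52 without gland 4 and at 0.70 and 0.64 without tumours 4 and 5 in turn. Of 22 p53 targets, 2 rose and 4 fell, 3 and 4 when adjusted over the list alone, and the list did not pass (median -0.06, camera adjusted p = 0.874). For change in either direction the list passed (mixed fry adjusted p = 1.74e-06). Perp, a desmosome-associated protein, rose by 5.60 ± 0.65, and Bax, which promotes apoptosis, by 1.38 ± 0.38. Tigar, Rrm2b and Sesn1 fell by 2.58, 1.01 and 1.11 on the log2 scale (adjusted p = 0.0129, 0.0334 and 0.0386), Tigar by 1.72 without gland 4. The calls of Bax, Rrm2b and Sesn1 were lost in 7, 6 and 7 of the 10 fits without 1 library, each of them without gland 1, 2 or 3, with adjusted p up to 0.0921, 0.0939 and 0.0908. Of 14 tumour suppressors and oncogenes, 3 rose, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0622). It passed under upper-quartile scaling (adjusted p = 0.0473), with no filter (adjusted p = 0.0466), and without tumour 1 (adjusted p = 0.0188) or tumour 4 (adjusted p = 0.0432), tumours 1 and 6 (adjusted p = 0.0114) or these and gland 4 (adjusted p = 0.0355). Ccnd1, the cyclin D1 gene, rose from 33.1 ± 2.59 CPM to 417 ± 249 CPM (log2 fold change 3.65 ± 0.57, adjusted p = 0.00457), and was higher in 6 of 6 tumours. Cdkn2a, which encodes inhibitors of cell cycle entry, rose by 5.25 ± 1.29 (adjusted p = 0.0234), with 64.1 and 54.9 CPM in tumours 4 and 5 and at most 7.61 CPM in the other tumours. Erbb2 rose by 1.53 ± 0.45 (adjusted p = 0.0409). The Cdkn2a call was lost without any 1 of the 4 glands and the Erbb2 call in 7 of 10 such fits, those without a gland or tumour 2, 4 or 6, with adjusted p up to 0.0772 and 0.111.

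**Figure D3:**
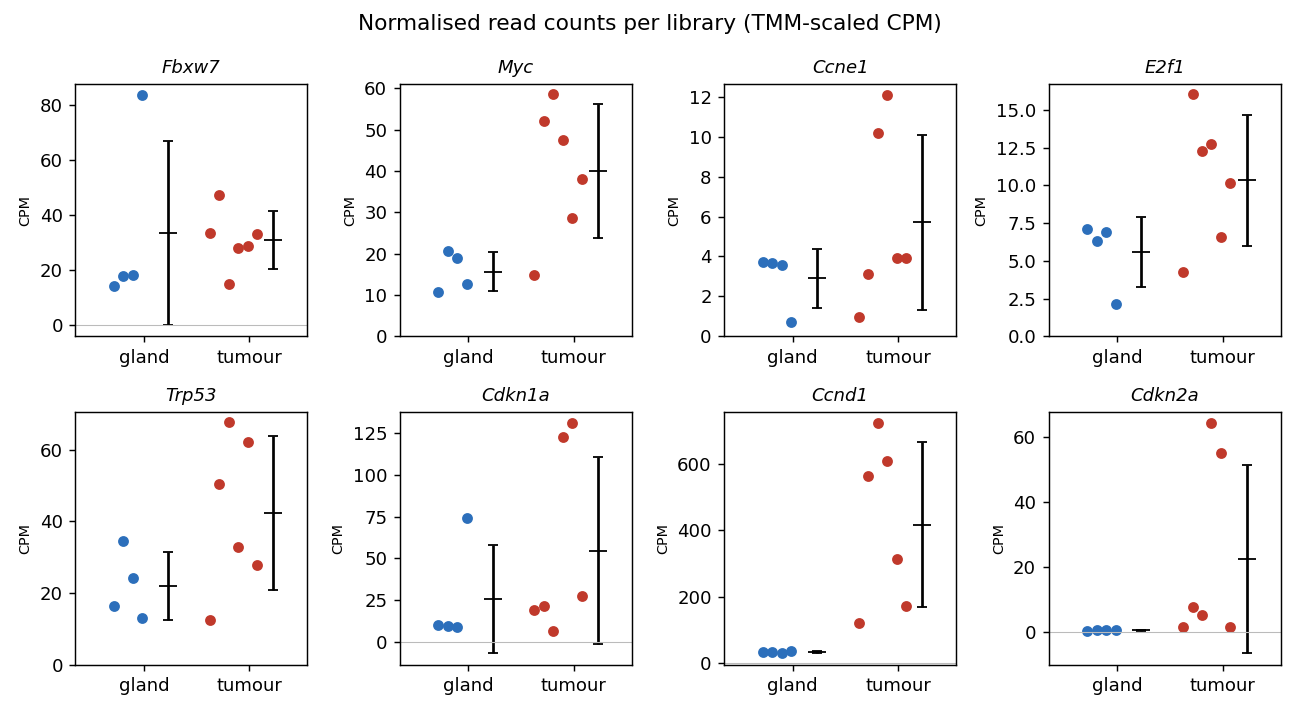
Normalised read counts (TMM-scaled CPM) of 8 genes in the 4 glands (blue) and 6 tumours (red), one point per library, with the mean and SD beside each group. Ccnd1 separates the groups, with a gland mean of 33.1 CPM and a tumour mean of 417 CPM, while Fbxw7 reaches 83.6 CPM in gland 4.

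Luminal epithelial markers rose in tumours, 8 of 10 over all genes and 9 when adjusted over the list alone, with a median log2 fold change of 2.21 (camera adjusted p = 1.78e-09, and adjusted p = 0.0745 with an estimated correlation). The adhesion gene Cdh1 rose by 2.49 ± 0.32, the tight-junction gene Cldn7 by 3.60 ± 0.48 and the protease inhibitor Spint2 by 2.57 ± 0.38 (adjusted p = 0.00255, 0.00291 and 0.00392). Of 12 tested milk and alveolar genes, 6 rose, 9 when adjusted over the list alone (median 4.35, camera adjusted p = 0.00367, 0.463 as adjusted p with an estimated correlation). These included Elf5, an alveolar transcription factor (3.49 ± 0.64), and the casein genes Csn1s1 (9.53 ± 2.04) and Csn3 (6.37 ± 1.44). Csn3 was not called without gland 1 or 2 (adjusted p up to 0.0573). Of 12 tested squamous markers, 5 rose, 6 when adjusted over the list alone (median 3.94, also with 1 member at 0 in a whole group set to its bound, camera adjusted p = 0.000307, and adjusted p = 0.463 with an estimated correlation). Dsg3, a desmosomal cadherin, rose by 8.44 ± 0.85. The mean log2 CPM of squamous markers in tumour 3, -1.88, lay within the range of the glands (-2.52 to -1.34). It was 0.354 to 3.30 in the other tumours. Of 9 basal and myoepithelial markers, the keratins Krt14 and Krt17 rose by 5.32 ± 1.10 and 5.41 ± 1.36 (adjusted p = 0.0129 and 0.0255), the latter not without any 1 of the glands (adjusted p up to 0.0709). Adjusted over the list alone, 3 rose and 1 fell, and the list did not pass (median -0.12, mean 1.47, camera adjusted p = 0.874).

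Hormone-sensing luminal markers fell, 3 of 10 over all genes and 3 with 1 higher when adjusted over the list alone (median -1.55, camera adjusted p = 0.00132, and adjusted p = 0.410 with an estimated correlation). The estrogen receptor gene Esr1 fell from 62.7 ± 6.28 CPM (SD, n = 4) to 5.27 ± 3.29 CPM (SD, n = 6), and was lower in 6 of 6 tumours (log2 fold change -3.58 ± 0.45, adjusted p = 0.00224). The progesterone receptor gene Pgr changed by -3.18 ± 0.67 and the prolactin receptor gene Prlr by -1.64 ± 0.32 (adjusted p = 0.0138 and 0.0109). Each of these 3 calls held in all 10 fits without 1 library.

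All 13 adipocyte markers fell, also when adjusted over the list alone, with a median log2 fold change of -6.15 (camera adjusted p = 2.32e-12, and adjusted p = 0.410 with an estimated correlation). Retn, the resistin gene, changed by -6.35 ± 1.19, Pparg, a regulator of fat cell differentiation, by -5.19 ± 1.04 and Plin1, a lipid droplet protein, by -6.15 ± 1.28 (adjusted p = 0.00903, 0.0112 and 0.0129). Of 12 skeletal muscle markers 8 fell, 12 when adjusted over the list alone and 1 with limma-voom (median -7.34, camera adjusted p = 0.000192, and adjusted p = 0.463 with an estimated correlation). Without gland 4 the median was -4.39, and over all fits without 1 library it was -8.22 to -4.39. Mb, the myoglobin gene, changed by -7.59 ± 1.90 (-4.39 without gland 4, -9.33 to -4.39 without 1 library) and was not called without gland 1, gland 4 or tumour 2 (adjusted p up to 0.0730). Fibroblast markers (2 of 10 fell, 3 over the list alone) and endothelial markers (3 of 9 fell, 3 over the list alone) also passed the set test, at medians of -1.66 and -1.34 (camera adjusted p = 0.000126 and 0.00184, and adjusted p = 0.463 for both with an estimated correlation). Without tumour 6 the fibroblast median was -2.97. Among them Pdgfra changed by -1.71 ± 0.44 and Kdr by -1.73 ± 0.44 (adjusted p = 0.0283 and 0.0270). Pdgfra was not called without gland 1 or 2 or tumour 4, and Kdr without gland 1, 2 or 3 or tumour 4 (adjusted p up to 0.0962 and 0.0713). No member of the brown fat, red blood cell or T and NK cell lists passed over all genes, although the lists did, at medians of -2.82, -1.65 and -3.23 (camera adjusted p = 0.0107, 0.0189 and 0.0265, and adjusted p = 0.463, 0.463 and 0.544 with an estimated correlation). Brown fat was at -4.28 without tumour 1 and red blood cell markers at -2.92 without tumour 6. Of these 3 lists 3, 0 and 6 members were lower at an unadjusted p below 0.05 in edgeR, 0, 0 and 5 when adjusted over the list alone, 4, 1 and 0 with limma-voom and 1, 0 and 6 with DESeq2. The T and NK cell list did not pass without gland 2 or 3 or tumour 1 or 3 (adjusted p up to 0.144). Its summed levels were 494 and 384 CPM in glands 2 and 3, 20.8 CPM in gland 1 and 2.92 CPM in gland 4. In the tumours they were 6.99 to 86.6 CPM, so the fall rested on glands 2 and 3. B cell markers did not pass (median -3.09, camera adjusted p = 0.0622, none of 8 called or called over the list alone in edgeR, 4 lower at an unadjusted p below 0.05, 0 with limma-voom and 3 with DESeq2; the list passed without gland 1, gland 4 or tumour 5, with -4.86 in the last), nor did macrophage markers (median 0.15, camera adjusted p = 0.874, test direction down), of which Cd14 rose by 3.40 ± 0.90, though not without any 1 gland or tumour 4 (adjusted p up to 0.0833). Only 4 neutrophil markers were testable, too few for the set test, with a median of 0.59 and none past the threshold in edgeR, also unadjusted, in limma-voom or in DESeq2.

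Beside the fall of all 13 adipocyte markers (median -6.15), lipid synthesis genes moved both ways, with 7 of 19 lower and 1 higher, 7 and 2 when adjusted over the list alone (median -0.32, camera adjusted p = 0.01, and adjusted p = 0.539 with an estimated correlation). The list did not pass without tumour 1 (adjusted p = 0.122), and its median was -0.026 without gland 1 and -0.52 without tumour 3. The genes Acaca, for the first step of fatty acid synthesis, Me1, a source of NADPH, and Elovl6, a fatty acid elongase, changed by -3.68 ± 0.58, -3.33 ± 0.42 and -2.29 ± 0.38 (adjusted p = 0.00464, 0.00224 and 0.00589). Sqle, of sterol synthesis, rose by 1.93 ± 0.59 (adjusted p = 0.0477), a call that held in 1 of the 10 fits without 1 library, the one without tumour 1, with adjusted p from 0.0139 to 0.111. The list of mesenchymal transition genes passed as lower (median -0.69, camera adjusted p = 0.0285, and adjusted p = 0.463 with an estimated correlation), but not without tumour 1 or 5 (adjusted p up to 0.107), nor with the stricter filter, age as a covariate or DESeq2, and its median was -0.18 without gland 1 and -1.22 without tumour 4. Its members went both ways. The transcription factors Zeb1, Prrx1 and Twist1 changed by -2.98 ± 0.68, -2.45 ± 0.56 and -2.61 ± 0.62, whereas the matrix protein genes Spp1 and Tnc rose by 9.0 ± 1.67 and 3.98 ± 0.81. The 3 transcription factors were not called without gland 1 (adjusted p up to 0.0690). Fibroblast and endothelial markers fell in the same libraries (medians -1.66 and -1.34). Of its 15 members 2 rose and 4 fell, 2 and 5 when adjusted over the list alone. Hypoxia and glycolysis genes (2 of 18 higher, 5 lower, 2 and 6 over the list alone, median -0.22), interferon response genes (none of 14 in edgeR, none over the list alone, 3 higher at an unadjusted p below 0.05, 0 with limma-voom and 3 with DESeq2, median 1.13) and immediate early genes (1 of 13 higher, 1 lower, the same counts over the list alone, median 0.63) did not pass as lists, with camera adjusted p of 0.113, 0.154 and 0.672, the first and second passing without tumour 4 (adjusted p = 0.0357 and 0.00721), and the immediate early median was 0.26 without tumour 6.

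By the rule that ranked called, well expressed and non-overlapping genes by fold change, the highest in tumours were Bpifa2, Smr3a, Wfdc12, Krt6b, Col2a1, Sprr2a2, Gpx2 and Krt6a. Bpifa2 and Smr3a are salivary transcripts that lay at or below 16.4 and 3.06 CPM in tumours 2 to 5. Gpx2, a glutathione peroxidase, rose from 0.0908 ± 0.0702 CPM to 72.9 ± 84.8 CPM, a log2 fold change of 9.81 ± 1.54 (SE, n = 4 and 6; adjusted p = 0.00460). Krt6a, a keratin of stratified epithelium, rose by 9.70 ± 1.79 (adjusted p = 0.00875). In tumour 3 Krt6a was at 0.124 CPM, against at most 0.111 CPM in the glands. Its neighbour in sequence Krt6b had 1 count over the 4 glands and 4471 over the 6 tumours. Of these, tumours 1 to 6 gave 53, 44, 1, 1096, 2075 and 1202. The 2 keratins are similar enough that reads may be divided between them. Wfdc12, a protease inhibitor, was at 0.472 ± 0.274 CPM in glands and 5373 ± 9317 CPM in tumours, with 23642 and 6703 CPM in tumours 1 and 6, where salivary transcripts were high, and 1.84 to 1836 CPM in tumours 2 to 5. The cartilage collagen gene Col2a1 was at 55.2 ± 99.7 CPM in tumours and the cornified envelope gene Sprr2a2, one of a family of close copies, at 44.3 ± 99.8 CPM. The SD of these 3 genes exceeded their mean. The calls of Bpifa2 (without gland 1 or 3), Wfdc12 (without gland 1, 2 or 3), Krt6b (without gland 2) and Col2a1 (without gland 1 or 2) were lost, with adjusted p up to 0.0729, 0.0678, 0.0610 and 0.0678. Those of Smr3a and Sprr2a2 were lost without any 1 gland, with adjusted p up to 0.120 and 0.0993. The lowest in tumours were Mup22, Mup16, Mup9, Pon1, Cyp2e1, Ces1f, Mup17 and Slc7a10, each called in all 10 fits without 1 library. Cyp2e1, a cytochrome P450 that oxidises small molecules, was at 1353 ± 932 CPM in glands and 4.27 ± 5.92 CPM in tumours (log2 fold change -8.32 ± 1.52, adjusted p = 0.00851). Pon1, an esterase, Ces1f, a carboxylesterase, and Slc7a10, an amino acid transporter, changed by -8.35 ± 1.30, -7.76 ± 1.19 and -7.21 ± 1.5. Mup genes encode major urinary proteins and are near-identical copies, so the division of reads among Mup9, Mup16, Mup17 and Mup22 is uncertain. Mup22 was at 8.01 CPM in gland 4 and between 868 and 2911 CPM in glands 1 to 3. Each of these lowest genes had its lowest gland value in gland 4. Adipocyte markers took 0.449% of the counts there, against 3.45% to 4.33% in glands 1 to 3. Whether these genes follow fat content was not tested.

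The series also lists 3 samples of purified epithelium at 16 weeks, 1 wild-type and 2 Fbw7-deleted. They were not analysed here, so neither the effect of the deletion in purified epithelium nor its difference from the tumour effect was tested.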

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

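All tests in this part were chosen after the values were seen, apart from the search for outlying libraries, its salivary marker list excepted. That search looked, in 76 groups of values, for a library whose gap to the nearest other exceeded Dixon's 95% critical value. It found 11, where chance alone gives about 3.80. The salivary flag is among these 11, but its marker list was chosen after the values were seen. That flag is therefore no independent test.

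Tumour 1 held the most salivary gland transcripts, with a gap of 0.647 of the range of the tumours (62.2% of counts against 0.0152% to 22.0%). Of 8 salivary markers not picked from these libraries, 5 were higher in both tumours 1 and 6 than in each of tumours 2 to 5, so salivary tissue is a candidate source, led by Bpifa2, Amy1 and Smr3a, but the markers move together, tumours 1 and 6 were picked for such transcripts, and tumour cells that express them stay open. Carried-over reads of tumours 1 and 6, or a trace of that tissue, would leave these markers at equal ratios in tumours 2 to 5. The ratios of the 8 most abundant listed markers spanned 79.8-fold through Car6 alone, which had 2377 counts in tumour 4. This argues against carry-over as the source of the Car6 traces. Of 20 markers 11 lay over 10 times the lowest ratio. They include Aqp5, Klk1 and Egf, which were above a mean of 1 CPM in the glands. Smr2 and Muc19, also among them, had few counts in tumours 1 and 6. The count of 11 is therefore no test of carry-over. The 7 most abundant agreed within 1.555-fold, a cut made after the ratios were seen, so for these carry-over and a trace of tissue cannot be told apart. Without Amy1, which was at 240 to 427 CPM in glands 1 to 3 and 66.8 CPM in gland 4, the other 7 of the 8 had 31 counts in gland 4 against 76 in glands 1 to 3 (exact binomial p = 0.104), without Dnase1, which gave most of the latter, 20 against 18 (exact p = 4.32e-05), and with the unlisted gene 2310057J18Rik in place of Car6 31 against 61 (exact p = 0.0118), so the outcome turns on the genes counted, and each p covers counting error only and rests on 1 library against 3: whether glands 1 to 3 were sequenced apart cannot be told apart from other differences of gland 4.

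Gland 4 stood apart in several values. Its mitochondrial share was 37.5% against 12.8% to 14.0% (gap 0.950 of the range of the glands). Its log2 CPM were 6.39 against 3.85 to 4.21 for Fbxw7 (gap 0.858), 6.21 against 3.10 to 3.33 for Cdkn1a (gap 0.927), -0.32 against 1.87 to 1.94 for Ccne1 (gap 0.970) and 1.18 against 2.68 to 2.84 for E2f1 (gap 0.900). Its mean log2 CPM of macrophage markers was 3.94 against 5.59 to 5.73 (gap 0.922). All 12 muscle markers had their highest gland value there, so skeletal muscle is a candidate source of the mitochondrial share. The markers vary together and do not test that link. In glands 1, 2 and 3 muscle shares were 1.73%, 0.805% and 0.00493% and mitochondrial shares 14.0%, 12.8% and 13.9%. These shares did not follow each other there. The age of 40 weeks, against 20 weeks in glands 1 to 3, and the sequencing batch were not tested as causes.

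In the remaining flags, tumour 1 was the lowest of the tumours in its mean log2 CPM of Fbxw7 substrate genes (3.87 against 4.74 to 5.17, gap 0.669 of the range) and in log2 CPM of Notch1 (2.48 against 4.62 to 5.76, gap 0.650). Tumour 3 was the lowest in hormone-sensing luminal markers (0.71 against 2.65 to 3.46, gap 0.705), and tumour 6 the highest in milk genes (9.46 against 3.15 to 4.85, gap 0.730).

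The rise of E2F targets and mitosis genes in tumours was set against changes in tissue make-up. A loss of fat and muscle cells alone would raise all other cell types alike. However, 18 of 19 fibroblast and endothelial markers had negative fold changes, with a median of -1.62. Their mean log2 CPM was lower in tumours by 2.34 (exact permutation p = 0.0190 over the libraries, since the markers vary together). Camera with estimated correlations gave an adjusted p of 0.463 for each list. These values argue against a loss of fat and muscle cells alone as the whole cause. Fibroblasts and vessels within fat and muscle would fall with that tissue, so these markers cannot decide whether the tissue as a whole was replaced. Between groups, the mean log2 CPM differed by 1.91 for E2F targets, by 3.13 for mitosis genes and by 2.14 for luminal markers (exact permutation p = 0.0286, 0.0143 and 0.00476). The excess over luminal markers was -0.23 for E2F targets (exact permutation p = 0.676) and 0.99 for mitosis genes (exact permutation p = 0.200), so a larger share of epithelial cells cannot be told apart from higher levels per cell for either list. A change with the tumour state itself stays open, untested.

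The count of 3030 genes was larger than that of the other splits drawn. Of 100 of the 210 splits of the libraries into 6 and 4, 1 gave as many genes, the real one. The highest of the other splits gave 18. Every other split put tumours and glands together in a group, which widens its spread, so low counts were likely there. The splits make a random grouping an unlikely source of the count, but do not exclude it. They cannot tell tissue make-up, age, genotype and a possible sequencing batch apart.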

How the results depend on the processing

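The 3 choices of libraries named below other than single ones were made after the data were seen. The alternatives for purified epithelium, the fit of all 13 samples and the pseudocounts were not run, since no value for those samples or units was at hand. The 40-week gland is gland 4, so leaving it out is one of the 10 fits without 1 library. No paired analysis was possible because replicate numbers only follow accession order. The cause of the shifts below was not tested, except that fewer libraries give fewer degrees of freedom. The count of 3030 genes was 1899 with age as a covariate, 5252 with DESeq2, 4640 without tumours 1, 6 and gland 4, 330 for tumours against gland 4 alone (whose spread is assumed to equal that of the tumours) and 1053 to 3521 over the fits without 1 library. Under RLE and upper-quartile scaling, no filter, a stricter filter, limma-voom, a 2-fold threshold and without tumours 1 and 6 it stayed within 1.5 times. Of the 88 named genes 80 were called, against 40 to 76 without 1 library. All but the 9 genes named whatever their test were chosen because they were called in the main fit. The count of 80 is therefore mostly set by the rule and is no result. Of 26 lists 16 passed, against 14 to 19 without 1 library, 0 with estimated correlations and 6 with fry. The E2F list (median 1.91, adjusted p = 0.463 with estimated correlation and 0.0570 with fry) and the Myc target list (median 0.75, adjusted p = 0.463 and 0.0644) lost their calls only in these 2 tests, and kept them without 1 library, at medians of 1.67 to 2.10 and 0.58 to 0.78.

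The log2 difference of Fbxw7 (-0.12) was 0.013 under upper-quartile scaling, 0.33 with limma-voom, 0.72 without tumours 1, 6 and gland 4, -1.38 against gland 4 alone, and -0.37 to 0.80 without 1 library, never past the threshold. The median of p53 targets (-0.06) was 0.077 under upper-quartile scaling, 0.0084 with the stricter filter, 0.11 with limma-voom, 0.070 without tumours 1 and 6, 0.33 without these and gland 4, 0.41 against gland 4 alone, and -0.20 to 0.19 without 1 library. Mdm2 turned to 0.073 under upper-quartile scaling, 0.076 without tumours 1 and 6 and 0.24 without these and gland 4, with -0.20 to 0.18 without 1 library. Jun ranged from -0.10 to 0.37 without 1 library, and Cdkn1a was -0.33 against gland 4 alone. The median of basal markers turned to 0.061 under upper-quartile scaling, 1.24 with the stricter filter and 0.11 against gland 4 alone, with -0.26 to 0.11 without 1 library. That of macrophage markers turned to -0.024 with limma-voom, -0.25 without tumours 1 and 6 and -0.65 without these and gland 4 (adjusted p = 0.0355), with -0.20 to 0.33 without 1 library. Hypoxia genes ranged from -0.46 to 0.013 without 1 library. Against gland 4 alone the medians were 0.033 for hypoxia genes, 1.01 for lipid synthesis, 0.17 for mesenchymal transition, 3.09 for T and NK cells and 4.45 for B cells. Set calls against gland 4 alone are not listed, since 1 library cannot be told apart from its group. Beside these and the fits without 1 library, set calls changed as follows. B cells passed under upper-quartile scaling and with no filter, hypoxia genes with no filter, and Notch targets without tumours 1 and 6 and without these and gland 4. T and NK cells did not pass with the stricter filter, age as a covariate, limma-voom or without tumours 1 and 6. The same held for red blood cells with the stricter filter or DESeq2, brown fat with DESeq2, and lipid synthesis without tumours 1 and 6. Counts of called members that moved by over 1.5 times were, with limma-voom, muscle 8 to 1 lower, milk 6 to 3 and squamous 5 to 2 higher, fibroblast 2 to 5 and endothelium 3 to 5 lower, and substrate genes and tumour suppressors and oncogenes each 3 to 1 higher, and with DESeq2, E2F targets 17 to 29, Myc targets 6 to 10, Notch targets 2 to 4 and p53 targets 2 to 4 higher, and fibroblast 2 to 4 lower; others changed by 1 member, or are given with the lists. Among the other 23 lists, 426 of 503 values kept direction and side of the threshold, 41 lost and 18 gained the call and 18 turned. Among the named genes, 1483 of 1836 kept both, 338 lost the call, 1 gained it and 14 turned. Since most of these genes were chosen as called, few could gain a call. Depth limits genes such as Krt6b, with 1 count over the glands.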

Other observations

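The test of gland position in this part was chosen after its values were seen, as were the genes named here. Of 25 tested Hox genes, which encode transcription factors of body position, 11 were lower in tumours and none higher (edgeR, adjusted p below 0.05), with a median log2 fold change of -3.16, and RLE and upper-quartile scaling gave 11 and 10 lower. Adipocyte, skeletal muscle and fibroblast markers fell in the same libraries (medians -6.15, -7.34 and -1.66), and the cells that express these Hox genes were not identified. Hoxc8 was at 54.0 ± 17.3 CPM in glands (SD, n = 4) and 3.32 ± 4.18 CPM in tumours (SD, n = 6), a log2 fold change of -4.02 ± 0.86 (SE; adjusted p = 0.0145). Hoxa7 changed by -4.22 ± 0.51 and Hoxa9 by -5.42 ± 0.87 (adjusted p = 0.00176 and 0.00523). Hoxb4 stood at 0.29 ± 0.94 (adjusted p = 0.843), with 42.4 CPM in tumour 4.

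The tumours differed among themselves. Cdkn1a was at 123 and 131 CPM in tumours 4 and 5 and at 6.28 to 27.6 CPM in the other tumours, and Cdkn2a was also highest in tumours 4 and 5. The interferon-induced genes Irf7 and Ifit1 were at 3.91 and 7.15 CPM in tumour 3 and at 4.19 and 3.41 CPM in tumour 4, against at least 44.6 and 22.9 CPM in the other 4 tumours. The summed level of milk genes was 34155 CPM in tumour 6 and 562 to 7779 CPM in the others. Basal markers summed to 4447 CPM in tumour 5 and to 116 CPM in tumour 3, where Krt5, a basal keratin, was at 0.148 CPM against 1222 CPM in tumour 5. The p53 target Pmaip1 was at 194 CPM in tumour 5 and at most 4.80 CPM in the others.

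The glands also differed among themselves. The B cell gene Cd79a was at 97.9 CPM in gland 2 and 79.1 CPM in gland 3, against at most 3.37 CPM in glands 1 and 4. Hoxc10, a posterior Hox gene, was at 15.02 and 15.87 CPM in glands 2 and 3 and at 0.599 and 0 CPM in glands 1 and 4. Of 6 tested Hox genes of the posterior groups 9 and 10 only 3 were higher in both glands 2 and 3, while Hoxa9, Hoxa10 and Hoxd9 were highest in gland 4 (9.28, 11.1 and 17.9 CPM). A hypothesis is that glands 2 and 3 were taken from another body position, with a lymph node, than glands 1 and 4. Of 7 tested Hox genes of the anterior paralogue groups 4 and 5, 4 were lower in both glands 2 and 3, between the bounds set for and against, so with 4 libraries the explanation may hold but was not decided.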
